A study of Saccharomyces cerevisiae BY4741 with 16 samples.

How the data were processed

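Chromatin immunoprecipitation followed by sequencing was used, per the labels, to follow trimethylation of histone H3 at lysine 4 (H3K4me3) and at lysine 36 (H3K36me3) in budding yeast, *Saccharomyces cerevisiae*, after RNA polymerase II (RNAPII) was removed from the nucleus. In the anchor-away method, rapamycin tethers a tagged nuclear protein to a ribosomal protein that carries FKBP12, and the ribosomal protein takes it out to the cytoplasm. The strain label names BY4741 with a RPL13 anchor, a *tor1* mutation and a deletion of *FPR1*, which keep rapamycin from acting through its usual target. It names no tagged polymerase subunit, so the depletion itself is taken from the series design. The labels list 16 libraries, 8 from immunoprecipitated DNA and 8 from input DNA, which makes 1 of each per mark and time at 0, 20, 40 and 60 min after rapamycin at 1 ug/mL. Cells of the fission yeast *Schizosaccharomyces pombe* were added at 25% as a spike-in, per the labels' protocols. The treatment and extract texts also mention RNA sequencing, which is not analysed here.

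The authors deposited 1 table of signal per gene, with a column for each mark and time. Per the submitters' processing notes, Bowtie2, SAMtools and bedtools were used with the builds sacCer3 and ASM294v2, and their versions and roles are not given in the sources used here. Whether the deposited signal was divided by input, by gene length or by the spike-in is not stated in the labels or the file headers, nor is the stretch of each gene that was measured. The column headings name a mark and a time but no library type, and each column was taken as the immunoprecipitated group of that mark and time. The values were linear, all above 0 and not whole, and showed no steps from which reads could be recovered. The depth behind each value is therefore unknown, and no interval from counting error is given.

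The table held 5222 lines below its headings. Of these, 3 were blank, 1 named a gene without values, and 5218 genes were used. Systematic names were matched to the R64 gene table, the assembly that sacCer3 also names. A match was found for 5115 genes and not for the other 103, which keep their systematic names and have no length or neighbours here. YPR169W-A and YPR170W-B carried identical values in every column. *LEU2*, *URA3* and the mitochondrially encoded genes are not analysed here.

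Log2 changes were computed as log2 of the level plus a pseudocount at the later time over the level plus the same pseudocount at 0 min. The pseudocount was 1% of the mark's median level at 0 min, 0.0491 for H3K4me3 and 0.0108 for H3K36me3, so changes of low genes are understated. Genes were kept when their mean level over the 4 times reached 25% of the median of such means, which left 4826 genes for H3K4me3 and 4861 for H3K36me3. With 1 library per mark and time there is no replicate error, so no p-value, standard error or count of changed genes is given, and medians and quartiles over genes describe these libraries. Slopes were least-squares fits of log2 level on time. For each of 18 gene lists, the median change was placed among 10000 random lists of the same size matched in 10 bins of mean level (seed 20). A list was described as apart from other genes when its percentile was below 2.5 or above 97.5, and lists with fewer than 5 members past the filter got no percentile. Correlations are Spearman's rho across genes, which are not independent replicates.

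The genes named were set by a rule. For each mark, among genes with a mean level at or above the median whose 20, 40 and 60 min values all lay on 1 side of the 0 min value, it took the 8 with the lowest and the 8 with the highest change at 60 min. It added the genes mutated in the strain, *ACT1* and *PMA1*, and up to 3 members of each list, namely the one with the highest mean level and those with the lowest and the highest change. Where several genes are given for a list, others are said to be chosen after their values were seen. The gene lists, the naming rule, the comparisons and most alternatives were set before the data were examined. The alternatives covered the pseudocount, the filter, column totals, a scaling to the lowest 5% of genes by mean level, each time left out, and the matching of random lists. A comparison of immunoprecipitated with input-corrected values was planned and not run, because the table has 1 column per mark and time.

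The steps were tested on simulated levels in which genes had a change of -0.5 on the log2 scale. From that value 200 genes were shifted up by 1, and noise of 0.2 was added to each level. Over 4834 simulated genes for H3K4me3 the estimated median was -0.48, 100% of 40 shifted lists of 12 genes were found, and 6% of 200 random lists lay outside the central 95%. For H3K36me3, over 4843 simulated genes, the estimated median was -0.48, 100% of 40 shifted lists were found, and 4.5% of 200 random lists lay outside. A shift of 1 is larger than that of any list placed below, so the simulation does not cover smaller shifts. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.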

Results

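H3K4me3, a mark of the start of transcribed genes, and H3K36me3, a mark laid down along gene bodies behind elongating polymerase, were measured at 0, 20, 40 and 60 min after rapamycin, with 1 library per mark and time. The question the series poses is how far each mark is lost once RNAPII has left the nucleus. The deposited signal of H3K4me3 summed to 23958, 23092, 24034 and 21240 over 5218 genes at the 4 times. That of H3K36me3 summed to 6655, 4822, 5034 and 4172. Across genes, levels at different times correlated with a rho of 0.914 to 0.970 for H3K4me3 and 0.906 to 0.964 for H3K36me3.

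Signal at the genes altered in the strain was read first, as a check of the labels. *FPR1*, which encodes the rapamycin-binding protein and is labelled as deleted, still had H3K4me3 signal of 2.26, 1.34, 3.86 and 1.04 at the 4 times, and H3K36me3 signal of 1.21, 0.0335, 0.240 and 0.185. Its 0 min H3K4me3 value was at percentile 12.5 of all genes, and its H3K36me3 value at percentile 56.0, but the 20 min H3K36me3 value was at percentile 0.0767. Such uneven values can be noisy ratios at low coverage, so whether the locus is empty was left open. *HIS3*, labelled with a mutant allele, had H3K4me3 of 6.81 at 0 min and 5.99 at 60 min, and H3K36me3 of 2.73 and 1.03. *TOR1* had H3K4me3 of 4.87 and 4.58 and H3K36me3 of 1.42 and 0.793 at these times. Of the paralogs *RPL13A* and *RPL13B*, either of which the anchor label could mean, H3K4me3 was 4.13 and 5.16 at 0 min and 3.45 and 3.47 at 60 min. Reads of such near-identical copies can be split between them, so their values are uncertain.

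H3K36me3 signal as deposited was lower after rapamycin at most genes. *NAB2*, which encodes a nuclear poly(A)-binding protein (chromosome VII), had the lowest change among genes with a mean level at or above the median whose 3 later times all lay on 1 side of 0 min, from 7.08 at 0 min to 1.89 at 20 min and 1.45 at 60 min, a log2 change of -2.28. *SER3*, which encodes an enzyme of serine synthesis and is known to be repressed by transcription of the upstream noncoding gene *SRG1*, was the highest of that set, and its region overlaps 1 other annotated gene. It went from 0.739 to 2.07, a log2 change of 1.47. The median gene stood at -0.41 at 20 min, -0.36 at 40 min and -0.65 at 60 min, or 63.5% of its 0 min level, with quartiles of -0.89 and -0.39 at 60 min.

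Within the same set of genes, *NAB2* was followed by *UTH1* (-2.07), *SND1* (-1.92), the histone deubiquitinase gene *UBP10* (-1.87), YLR278C (-1.86), the folate enzyme gene *ADE3* (-1.86), *SPT8* of the SAGA complex (-1.84) and the glycerol synthesis gene *GPD2* (-1.83). Within it, *SER3* was followed by YLR286W-A (0.69), the mRNA 3' end processing gene *HRP1* (0.47), the plasma membrane proton pump gene *PMA1* (0.42), YFL057C (0.41), *ICS2* (0.36), *GTS1* (0.35) and the ribosomal protein gene *RPS22B* (0.34). YLR286W-A and YFL057C had no match in the R64 table, so overlap with other genes was not checked there. Genes outside that set had larger changes, such as *QCR8* at -2.38 and the cell wall protein gene *CCW12*, chosen after its value was seen, at 1.65. *ACT1*, the actin gene, had H3K36me3 of 2.27 at 0 min and 1.16 at 60 min. Of the 4861 genes, 79.6% were below their 0 min level at all 3 later times and 2.94% were above it. Such comparisons, here, below and in the naming rule, share the single 0 min library of the mark. Agreement of the 3 times is therefore not separate evidence.

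These directions rest on the scale of each library. When each time was scaled so that the lowest 5% of genes by mean level kept their 0 min median, 60 min H3K36me3 changes moved up by about 0.61 and H3K4me3 changes by about 0.30. The share of genes below their 0 min level at 60 min was 95.2% as deposited and 54.8% so scaled for H3K36me3, and 88.7% and 22.8% for H3K4me3. Whether those lowest genes lack the marks is not known. The 8 lowest and 8 highest genes of each mark named by the rule kept their direction, as shifts of this size could not turn them. Of the list medians at 60 min, 13 of 15 for H3K4me3 and 11 of 16 for H3K36me3 changed sign. So did 19 of 63 and 12 of 65 of all genes named by the rule. Gene lists are therefore given relative to the median gene of the same mark, which a single scale factor leaves nearly as it was.

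**Figure D1:**
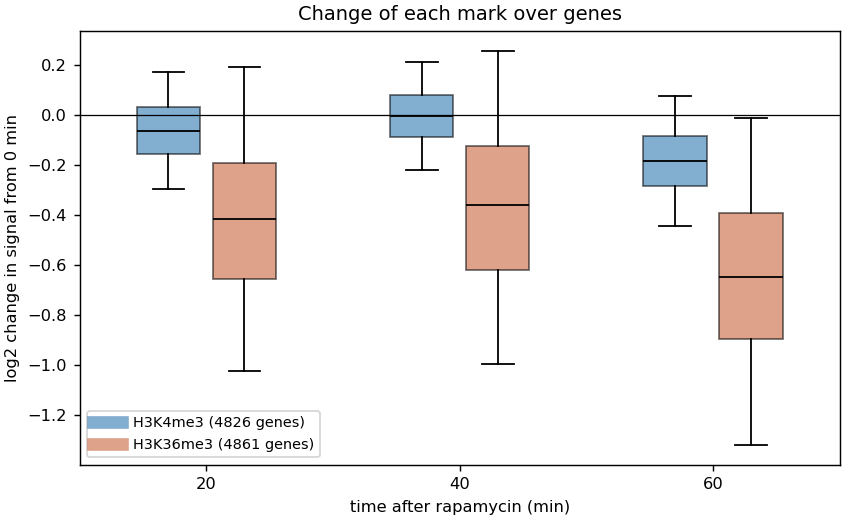
Log2 change of deposited signal from 0 min (vertical axis) at 20, 40 and 60 min after rapamycin (horizontal axis, min) for H3K4me3 (blue, 4826 genes) and H3K36me3 (orange, 4861 genes). Boxes are quartiles over genes with the median as a line, and whiskers reach the percentiles 5 and 95. The H3K36me3 median was -0.65 at 60 min and the H3K4me3 median -0.18, and these became -0.04 and 0.11 when scaled to the lowest 5% of genes.

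As deposited, the median H3K36me3 difference was mostly there at 20 min, but genes varied. *NAB2*, *SPT8* and *UTH1* each had lower levels at 20 min than at 0 min by a wide margin (4.16 and 1.54 for *SPT8*, 3.32 and 1.23 for *UTH1*), and smaller differences from there to 60 min. *SND1*, *UBP10* and *ADE3* were at -0.86, -0.83 and -0.88 at 20 min and at -1.92, -1.87 and -1.86 at 60 min, so the larger part came after 20 min there. The median gene differed by 0.05 between 20 and 40 min and by -0.28 between 40 and 60 min. The median slope over the 4 times was -0.57 log2 units per hour, with quartiles of -0.80 and -0.32. Without the 0 min library it was -0.34, so that library alone moved the value by more than 1.5 times.

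Among the gene lists, H3K36me3 of the histone genes was far above the median gene at 60 min, and that of the ribosomal protein genes was below it. The histone genes had a median change of -0.10, which is 0.55 above the median gene and at percentile 99.97 of random lists, with 4 of 10 members above their 0 min level. *HTA1*, which encodes histone H2A, went from 0.204 to 0.536, a change of 1.34. Its 0 min level was low, at percentile 4.29 of all genes. It was below the 0.219 that the mean over the 4 times had to reach. The variant gene *HTZ1* had the lowest change (-0.83) and the linker histone gene *HHO1* one of -0.79. The other core histone genes, chosen after their values were seen, went both ways. *HHF1* was at 0.58, *HTA2* at 0.42 and *HHT1* at 0.06. *HTB2* was at -0.48, *HHF2* at -0.35, *HTB1* at -0.16 and *HHT2* at -0.03. The cytosolic ribosomal protein genes had a median of -0.80, which is -0.16 relative to the median gene (percentile 0.01). Of their members 131 of 135 were lower than at 0 min, as were 95.2% of all genes. *RPL38* was at -1.79 and *RPS8A* at -0.69, and *RPS22B*, whose region overlaps another gene, was at 0.34.

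H3K36me3 of the glucose-repressed carbon source genes was 0.42 above the median gene (percentile 99.54, 8 members), with *FBP1* of gluconeogenesis at 0.03, *ADH2* at -0.35 and *SUC2*, the invertase gene, at -0.80. The amino acid biosynthesis genes were 0.15 above it (percentile 99.12), and 52 of 56 members were lower than at 0 min, from *TRP1* at -1.36 to *SER3* at 1.47, with *ILV5* at -0.39. The 5 measured genes altered in the strain were -0.65 relative to it (percentile 0.115), with *FPR1* at -2.64 (an uncertain value, as above), *HIS3* at -1.40, *RPL13B* at -1.30, *RPL13A* at -1.05 and *TOR1* at -0.84. Of 16 lists placed, 5 lay outside the central 95%, where 0.8 would if genes of a list varied independently, which was not tested. At 40 min 2 lists lay outside, and the histone, ribosomal protein, glucose-repressed and amino acid lists were inside, at percentiles 82.3, 76.3, 81.3 and 60.5. Without the 0 min library, in the change from 20 to 60 min, an alternative chosen for lists after seeing the data, only the strain genes of these 5 lists lay inside (percentile 29.3). The histone, ribosomal protein, glucose-repressed and amino acid lists stayed outside, at percentiles 100, 0.0, 99.89 and 99.53. When scaled to the lowest 5% of genes, the medians of the histone, glucose-repressed and amino acid lists became 0.51, 0.38 and 0.11, and that of the ribosomal protein genes remained negative at -0.19.

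The other 11 lists lay inside the central 95% for H3K36me3 at 60 min. Glycolysis and ethanol fermentation genes stood 0.13 above the median gene (percentile 95.9), with *TDH3* at 0.29, *FBA1* at -0.07 and *PFK2* at -0.98. General stress response genes stood 0.14 above it (percentile 93.4), with *PNC1* at 0.16 and *SOD2* at -1.22. In the change from 20 to 60 min, chosen after seeing the data, both lists lay above, at percentiles 99.83 and 99.8. So did the glycolysis genes with random lists matched on 0 min level (98.29) and the stress genes with no filter (98.99). All 33 proteasome genes were lower than at 0 min, with *RPN6* at -1.50 and *RPN12* at -0.18, and their list was at percentile 16.0. So were all 12 RNA polymerase II subunit genes, from *RPC10* at -1.65 to *RPB10* at -0.14 (percentile 75.8), and all 27 genes of the H3K4 and H3K36 methylation machinery, with *LGE1* at -1.44 (percentile 80.4). Of all genes past the filter 95.2% were lower as deposited, so these counts do not set such lists apart. Scaled to the lowest 5% of genes, 24 of 33, 6 of 12 and 12 of 27 members of these lists were lower. The methylation machinery genes had been above all 10000 random lists at 20 min. Ribosome biogenesis genes were at percentile 47.2 at 60 min, at 98.5 at 20 min and at 1.93 in the change from 20 to 60 min. At 20 min the ribosomal protein genes were above too (97.65). At 60 min came respiratory chain and ATP synthase genes at 12.6, pheromone response genes at 80.2, meiosis and sporulation genes at 88.1 (97.88 at 40 min), nitrogen catabolite and TOR-sensitive genes at 88.0 and housekeeping genes at 84.9. *NOP1* of ribosome biogenesis was at -1.05, *QCR8* of the respiratory chain at -2.38 and *GLN1* of nitrogen metabolism at 0.23. Silent mating-type and subtelomeric genes had 2 members past the filter and got no percentile.

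**Figure D2:**
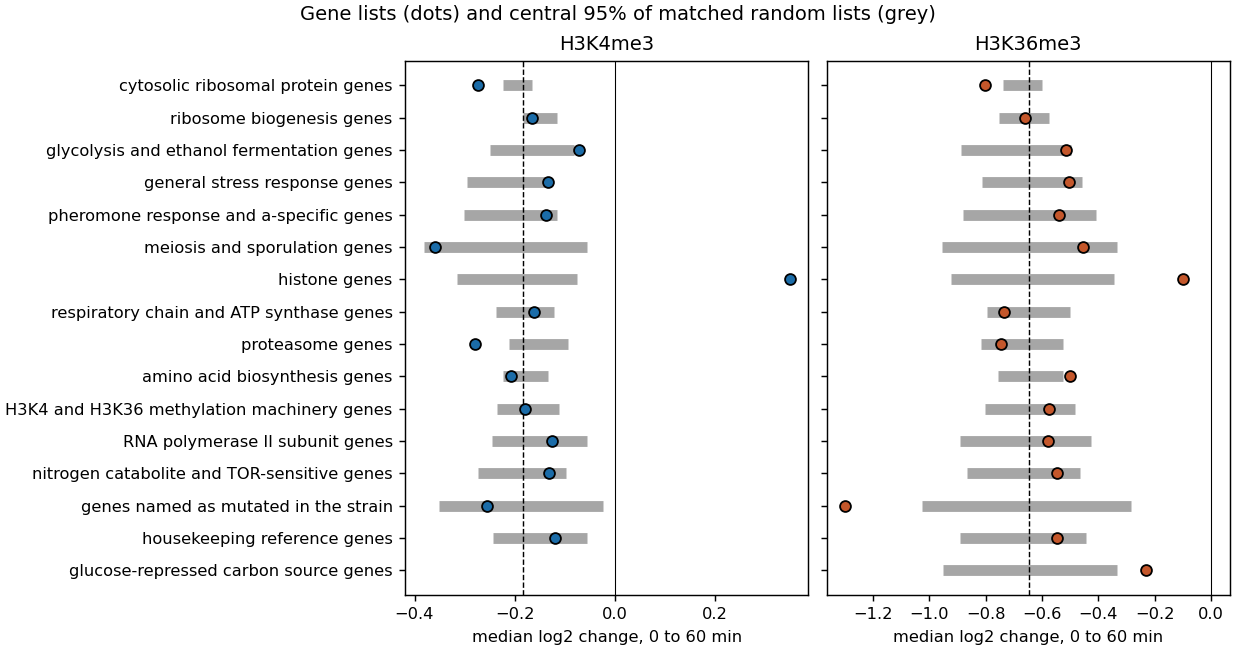
Median log2 change of deposited signal from 0 to 60 min (horizontal axis) of each gene list (vertical axis), for H3K4me3 on the left and H3K36me3 on the right. Dots are list medians, grey bars the central 95% of 10000 random lists matched on level, and dashed lines the median gene. Histone genes lie above the grey bar in both marks and ribosomal protein genes below it. Scaling to the lowest 5% of genes shifts each panel as a whole, by 0.30 and 0.61.

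Whether strongly marked genes lost more H3K36me3 was asked across genes. *NAB2* and *NOP1*, at 7.08 and 6.13 among the highest at 0 min, had changes of -2.28 and -1.05, while *HTA1*, at 0.204, had one of 1.34. Across 4861 genes the change at 60 min and the level at 0 min had a rho of -0.25, and the median change was -0.51 in the lowest 20% of genes by 0 min level and -0.80 in the highest 20%. The 0 min library stands on both axes there. With the change from 20 to 60 min the rho was 0.08, and with the level at 20 min on the axis, an alternative chosen after seeing the data, it was -0.0044.

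H3K4me3 signal as deposited differed less between times than H3K36me3, and genes with large differences lay on both sides. Among genes with a mean level at or above the median whose 3 later times all lay on 1 side of 0 min, *HRP1* had the highest change, from 3.47 at 0 min to 5.27, 7.20 and 7.40, a log2 change of 1.08. YML018C had the lowest of that set, from 6.17 to 3.52, a change of -0.80. The median gene stood at -0.06, -0.0024 and -0.18 at the 3 later times, or 88.0% of its 0 min level at 60 min, with quartiles of -0.28 and -0.08.

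Within the same set, *HRP1* was followed by YDR524C-B (0.95), *SPO24* (0.94), YDR133C (0.67), the pyruvate decarboxylase gene *PDC1* (0.63), *PMA1* (0.59), *NRD1*, which acts in termination of noncoding transcripts (0.53), and the peroxiredoxin gene *AHP1* (0.48). *PMA1* was highest at 40 min, at 8.71, against 5.07 at 0 min and 7.66 at 60 min. At the other end, YML018C was followed by *SND1* (-0.76), the chorismate mutase gene *ARO7* (-0.73), *FLC1* (-0.73), the heat shock factor gene *HSF1* (-0.70), the S-adenosylmethionine permease gene *SAM3* (-0.63), the repressor gene *CUP9* (-0.61) and *IGO1* (-0.60). Genes outside that set had larger changes, such as *SER3* at 2.06 and *RCO1* at -1.50. *ACT1* was at -0.53, from 3.53 to 2.43. Of 4826 genes, 41.0% were below their 0 min level at all 3 later times and 7.07% above it.

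The H3K4me3 difference of the median gene stood mostly in the 60 min library, but genes varied. *CUP9* was at -0.42 at 20 min and -0.61 at 60 min, and *SAM3* at -0.36 and -0.63. *HRP1* was at 1.04 at 40 min and 1.08 at 60 min. *SND1* had 5.99, 5.46 and 5.20 at 0, 20 and 40 min and 3.50 at 60 min, and YML018C 4.94 at 40 min and 3.52 at 60 min. Between 40 and 60 min the median gene differed by -0.18, and 96.4% of genes were lower. The median slope was -0.15 log2 units per hour, with quartiles of -0.25 and -0.05, and -0.0036 without the 60 min library. Across genes the change and the 0 min level had a rho of 0.07, and with the 20 min level on the axis, chosen after seeing the data, one of 0.19.

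The histone genes also stood apart in H3K4me3, with 7 of 10 members above their 0 min level at 60 min and a median change of 0.35, above all 10000 random lists. *HTA1* went from 1.60 to 3.70, a change of 1.19, and *HHO1* and *HTZ1* were at -0.14 and -0.06. Among genes chosen after their values were seen, *HHT1* of histone H3 was at 0.63, *HTB1* of histone H2B at 0.49, *HHF1* of histone H4 at 0.41 and *HTA2* at 0.40. The other copies were lower, with *HTB2* at 0.30, *HHF2* at 0.17 and *HHT2* at -0.09. Histone genes come in near-identical copies, and how their reads were split is not stated. It was the 1 list of the 15 placed that lay above the central 95% at 20, 40 and 60 min alike.

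Ribosomal protein and proteasome genes had lower H3K4me3 changes than all 10000 random lists. The former had a median of -0.27, which is -0.09 relative to the median gene, with 129 of 135 members lower than at 0 min, *RPS13* at -0.69, *RPS22B* at -0.05 and *RPL41A* at 0.23. At 20 min the list lay on the other side, at percentile 98.0. All 33 proteasome genes were lower than at 0 min, with a median of -0.28, *RPT3* at -0.55 and their regulator *RPN4* at -0.07. Of all genes past the filter, 88.7% were lower in H3K4me3 at 60 min as deposited. In the change from 20 to 60 min, without the 0 min library, the proteasome genes lay inside (percentile 8.32). Scaled to the lowest 5% of genes, the medians of both lists turned to 0.02.

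Glycolysis and ethanol fermentation genes stood 0.11 above the median gene in H3K4me3 (percentile 98.65), with 10 of 17 members lower than at 0 min, *PDC1* at 0.63, the aldolase gene *FBA1* at 0.28 and *PFK2* at -0.70. General stress response genes stood 0.05 above it (percentile 98.24), with *HSP42* at 0.58, *SOD2* at -0.20 and *GPP2* at -0.36. Both medians were negative as deposited, at -0.07 and -0.13, and positive when scaled to the lowest 5% of genes, at 0.23 and 0.16. Among genes that overlap no other gene, both lists lay inside, at percentiles 89.4 and 97.1. So did the glycolysis genes in the change from 20 to 60 min (percentile 88.5), and the stress genes when random lists were matched on 0 min level (percentile 94.6).

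The other 10 lists lay inside the central 95% at 60 min. The 5 lists outside compare with 0.75 if genes of a list varied independently, which was not tested. At 40 min 8 lists lay outside, and at 60 min 3 did among genes that overlap no other gene. Ribosome biogenesis genes were at percentile 19.2 (0.06 at 20 min, 0.65 at 40 min, and 98.2 in the change from 20 to 60 min, chosen after seeing the data), with *NOP4* at 0.17 and *NOG2* at -0.46. Respiratory chain and ATP synthase genes were at 70.8 (98.53 at 40 min), with *SDH4* at 0.28 and *QCR6* at -0.55. Amino acid biosynthesis genes were at 8.91 (2.44 at 40 min), and held *SER3*, which went from 1.45 to 6.18, a change of 2.06, beside *ARO7* at -0.73. Genes of the methylation machinery were at 38.5, with *PAF1* of the polymerase-associated factor complex at 0.06 and *RCO1* of the Rpd3S deacetylase, whose region overlaps another gene, at -1.50. RNA polymerase II subunit genes were at 68.0, with the largest subunit's gene *RPO21* at -0.07 and *RPB5* at -0.40. Nitrogen catabolite and TOR-sensitive genes were at 89.8, with *CIT2* at 0.88 and *GAT1* at -0.54. Pheromone response genes were at 93.0, with *MFA2*, a pheromone gene, at 1.04 and *STE5* at -0.52, meiosis genes at 5.33 (2.35 in the change from 20 to 60 min), housekeeping genes at 72.2 (99.69 at 20 min) and the strain genes at 20.8. Glucose-repressed genes and silent and subtelomeric genes had 4 and 2 members past the filter and got no percentile.

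Both marks were then set side by side at the same genes. *NAB2* had a change of -2.28 in H3K36me3 and -0.15 in H3K4me3, and *SND1* of -1.92 and -0.76. *HRP1*, *PMA1*, *SER3* and *HTA1* were above their 0 min level in both. The H3K4me3 change exceeded the H3K36me3 change at 90.1% of 4657 genes at 60 min, by a median of 0.47, and by 0.35 and 0.36 at 20 and 40 min. Scaled to the lowest 5% of genes, chosen after seeing the data for this comparison, the median difference at 60 min was 0.16.

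Genes with a higher change in one mark tended to have a higher change in the other. At *SPO24* the changes were 0.94 and 0.96 for H3K4me3 and H3K36me3, and at *CIT2* 0.88 and 0.14. *PDC1* had 0.63 and -0.31, so the marks went opposite ways there as deposited. Across genes the changes had a rho of 0.18, and the levels one of 0.73 at 0 min and 0.69 at 60 min. Both marks were below their 0 min level at all 3 later times at 1555 genes and above it at 21, where independent marks would give 7.98.

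**Figure D3:**
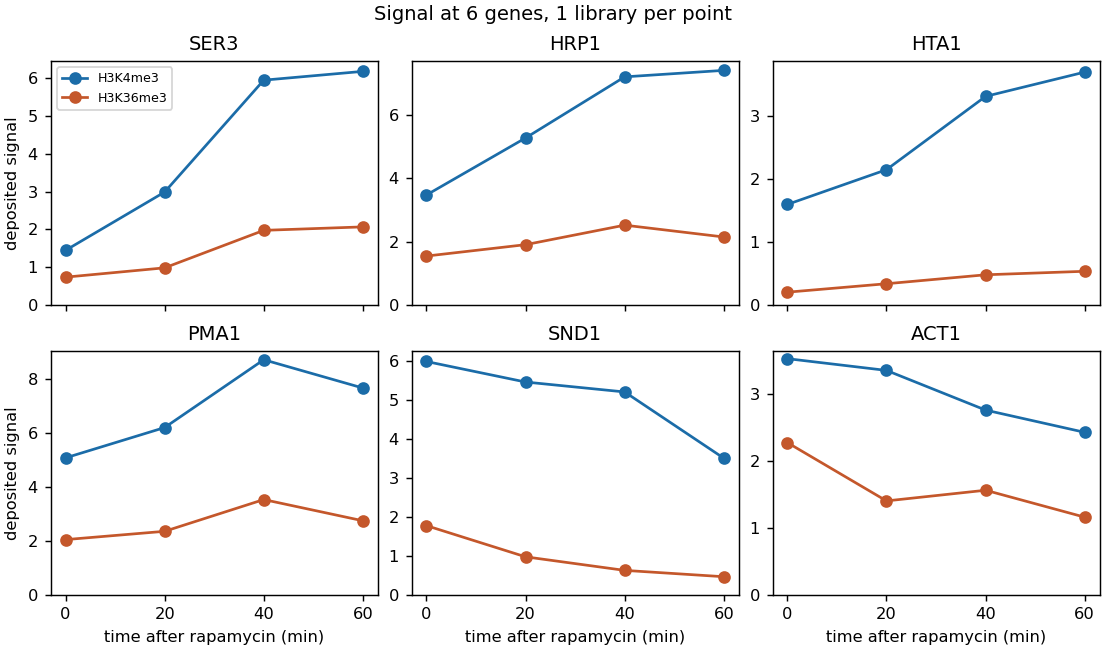
Deposited signal (vertical axes, each from 0) of H3K4me3 (blue) and H3K36me3 (orange) against time after rapamycin (horizontal axis, min) at 6 genes, with 1 library per point. *SER3*, *HRP1*, *HTA1* and *PMA1* were higher at 60 min than at 0 min in both marks, and *SND1* and *ACT1* lower in both, also when scaled to the lowest 5% of genes.

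**Figure D4:**
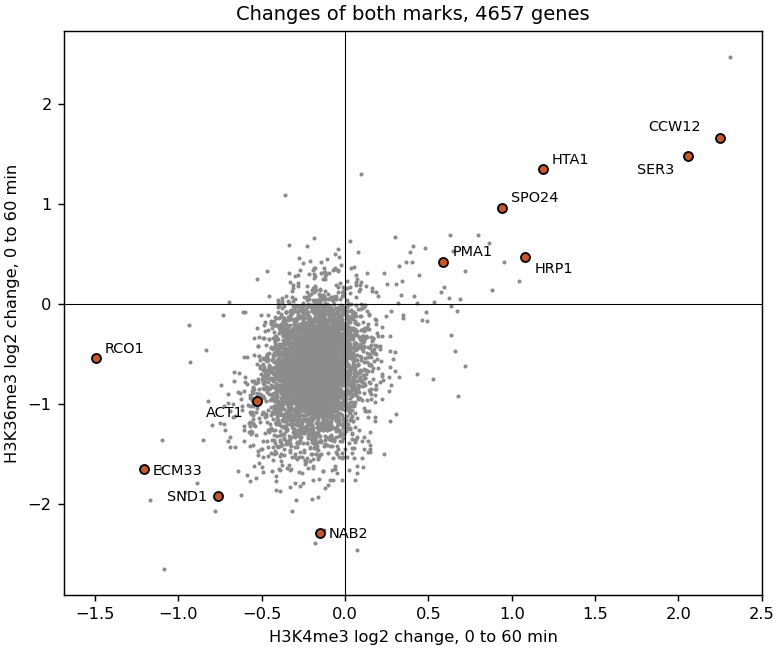
Log2 change from 0 to 60 min of H3K4me3 (horizontal axis) against that of H3K36me3 (vertical axis) at 4657 genes, 1 point per gene, with a few genes named. *SER3*, at 2.06 and 1.47, lies far outside the main cloud.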

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

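Of the tests in this part, those of the H3K4me3 library at 0 min, of the chromatin sample at 0 min, of library scale and of the 0 min library on both axes were chosen only after the result was seen.

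At 237 of 4657 genes, H3K4me3 was above and H3K36me3 below its 0 min level at all 3 later times, so the marks moved in opposite directions there. Independent marks would give 260, so the count was below that number. The difference was not tested, since each mark and time had 1 library, and the count depends on the scale of each library. Examples chosen after their values were seen are the mitochondrial ribosomal protein gene *MRP2*, at 0.07 for H3K4me3 and -2.45 for H3K36me3, *RPL41A* (0.23 and -1.50) and the chaperonin gene *CCT6* (0.14 and -1.47).

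Genes with the highest H3K4me3 changes mostly had higher H3K36me3 too. The 25 genes with the highest H3K4me3 change, among them *SER3*, *HTA1*, *HRP1* and *PMA1*, had a median H3K36me3 change of 0.33, at percentile 100 of random lists, and 24 of them were above the median gene but only 19 above their own 0 min level. Noise in the H3K4me3 library at 0 min would leave a separate H3K36me3 library in place, so these values argue against it. Among genes overlapping no other gene the percentile was again 100, with a smaller median of 0.14 and 17 of 25 above their 0 min level. Overlap was counted only against R64 genes, not the 103 unmatched ones. Reads shared with those or with close neighbours therefore stay possible. The chromatin sample at 0 min does not account for the higher changes alone. The H3K4me3 change from 20 to 40 min, from libraries that did not pick the genes, was at percentile 100 and higher in 25 of 25 genes. At 20 min, however, the H3K36me3 median change of the 25 genes was -0.23, with 9 of 25 above their 0 min level. That median was still at percentile 99.2 of random lists. These values are in line with a difference in chromatin at these genes over the time course, as a hypothesis found and examined on the same data, and normalization by the authors stays open.

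H3K36me3 was lower at 95.2% of genes at 60 min. The 261 genes with the lowest mean H3K36me3 level had a median change of -0.57 beside -0.65 for the genes past the filter. A scale factor would give such close medians, but so would an equal fractional loss at all genes. Whether the 261 genes lack the mark is not known, so these values cannot tell scale from such a loss. At 20 min the 261 genes were at -0.26 beside -0.41, further apart than the limit of 0.1 set for the test at 60 min. At 40 min they were at -0.30 beside -0.36, within that limit. The pseudocount understates changes of low genes, and without it the 261 genes were at -0.29 at 20 min. The limit was chosen after the result was seen, so these gaps do not decide how much of the shift is scale. A single factor per library cannot produce the spread between genes, from -2.28 at *NAB2* to 1.47 at *SER3* among genes named by the rule. Noise of single libraries of unknown depth can add to such a spread and was not measured. The value of *NAB2* rests on its 0 min level of 7.08, as the later levels were 1.89, 1.89 and 1.45. Removal of RNAPII, the treatment of the series, stays open as the cause of the shift and was not tested against scale, because how the spike-in entered the values is not stated.

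H3K36me3 changes were lower at genes with a higher 0 min level, as at *NAB2*. With the level at 20 min on the axis, a library on neither side of the change, the rho was -0.0044 in place of -0.25. A shared 0 min library may therefore account for the relation, and no biological explanation was tested.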

How the results depend on the processing

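With no replicates, values within 0.1 of the reported one (counts within 1.5 times) were taken as unmoved, and the cause was not tested where one moved. Of 81 alternative values other than single lists, 66 were unmoved. Pseudocount, filter and column totals kept the medians of both marks within 0.1. Scaling to the lowest 5% of genes gave H3K4me3 medians of 0.12 at 40 min and 0.11 at 60 min, against -0.0024 and -0.18, and H3K36me3 medians of -0.16, -0.13 and -0.042 at 20, 40 and 60 min. Without the 60 min library the H3K4me3 slope was -0.0036 per hour, and without the 0 min library the H3K36me3 slope was -0.34. From 0 to 40 min, 8 lists lay outside the central 95% for H3K4me3 and 2 for H3K36me3, against 5 each, and the difference between the marks was 0.36. From 20 to 60 min the rho of H3K36me3 change with starting level was 0.083, against -0.25. Of 90 comparisons of single lists for H3K4me3, 80 kept their place, and of 96 for H3K36me3, 82 did. For H3K36me3, glycolysis and stress genes turned to -0.00057 and -0.026 relative to the median gene from 0 to 40 min. Alternatives chosen after seeing the data gave 3 H3K4me3 lists outside among genes overlapping no other gene, rho values with the 20 min level of 0.19 for H3K4me3 and -0.0044 for H3K36me3, a difference between the marks of 0.16 with scaling to the lowest 5% of genes, and -0.042 for H3K36me3 of pheromone response genes from 20 to 60 min. Centring each time on the median gene would set the medians near 0 by construction and was not run. Ranking by slope kept 6 of the 8 lowest genes for H3K4me3 and 7 of 8 in each of the other groups. Input-corrected values were not run. With 1 library per group there were no replicate pairs to block on, and the marks were compared at matched times. Unknown depth limits every value of low genes.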

Other observations

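The test of high transcription in this part was chosen only after its result was seen, as were the rule that glycolysis genes lying above leave it open and the rule that too few distant pairs decide nothing, and the others were set before theirs were.

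The genes of this paragraph were chosen after their values were seen and stand for no group. *CCW12*, which encodes an abundant cell wall protein, went from 1.25 at 0 min to 6.13 at 60 min in H3K4me3 and from 0.444 to 1.42 in H3K36me3, with log2 changes of 2.25 and 1.65. *PIR1* and *HSP150*, of the same class of wall proteins, were at 0.87 and 0.67 in H3K4me3, and *CTS1*, the chitinase gene of cell separation, at 0.69. *ECM33*, which also acts in wall integrity, went the other way, from 4.78 to 2.04 in H3K4me3 and from 2.04 to 0.641 in H3K36me3. YMR013W-A, which had no match in the R64 table, had the highest H3K4me3 change of all genes past the filter, at 2.31, from a low 0.354 at 0 min.

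Histone genes and other cell cycle genes were then compared. A hypothesis that more cells were in M/G1 at 60 min was examined with 18 M/G1 genes past the filter. Their H3K4me3 median was 0.16 above the median gene at percentile 99.99. Of the 18, 7 were above their 0 min level and 13 above the median gene. *EGT2* was at 0.35, *AMN1* at 0.30 and *ASH1* at 0.24, but *TEC1* at -0.54, *MCM3* at -0.34 and *RME1* at -0.25. If H3K4me3 followed cell cycle stage, which was not tested here, more cells in G1/S would raise the 30 G1/S genes. These were at percentile 0.18, with *CDC9* at -0.53 and *POL12* at -0.42, though *PCL1* was at 0.35 and *RNR1* at 0.22. In H3K36me3, where the histone genes also stood apart, the M/G1 genes were inside at percentile 96.8 and the G1/S genes at 12.1. In H3K4me3 the M/G1 list thus lay above random lists and the G1/S list below. Histone genes are themselves known for expression in S phase, so a high M/G1 list cannot decide why they stood apart. Cell cycle stage is not analysed here.

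*HRP1* and *NRD1*, both near the top in H3K4me3, are known to be controlled by early termination of their own transcription. The hypothesis that such attenuation raises H3K4me3 here was examined with the other attenuated genes *URA2*, *URA8*, *ADE12*, *ROX1* and *CLN3*, which passed the filter. Their median was at percentile 69.4, with *ROX1* at 0.17 and *ADE12* at -0.53, which with 5 genes decides neither way.

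High transcription as the reason for higher marks at a few genes was examined with the ribosomal protein genes, among the most transcribed in growing cells. Their H3K4me3 median was at percentile 0.0 of random lists, below every one, although it had been above most of them at 20 min (98.0). Glycolysis genes, also highly transcribed, were above, at percentile 98.65, but inside among genes overlapping no other gene (89.4) and from 20 to 60 min (88.5), both chosen after seeing the data, where the ribosomal protein genes stayed at 0.0. High transcription thus did not go with higher H3K4me3 at 60 min in the ribosomal protein class, and whether it does at other genes is left open.

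Adjacent genes had H3K4me3 changes with a rho of 0.05 over 3837 pairs, where 95% of 1000 shuffles lay between -0.03 and 0.03. Pairs more than 500 bp apart had a rho of 0.025 over 979 pairs, within their shuffles of -0.07 to 0.06. The rho of all pairs would lie within these shuffles too, so the distant pairs were too few to decide whether gene regions that share reads account for the small relation.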
